A study of Mus musculus with 6 samples.

How the data were processed

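Total RNA of 6 samples of the integrin alpha7 inducible C2C12 line, 3 noninduced and 3 induced with tetracycline, was labelled with biotin and hybridised to 1 Affymetrix Mouse 430 2.0 array each; the chip type is per the file headers and the labelling per the labels' protocols. The deposited values are a linear signal intensity per probe set, 1 value per array, which the authors made with GCOS 1.1.1, per the submitters' processing notes; the signal algorithm's settings and the detection calls are not given in the sources used here. That each array was scaled to a common level was read from the values: the mean signal after trimming 2% at each end was 150.0 on every array. Such scaling makes each value relative to the whole array, so a change common to most transcripts would not show. The deposited experiment records of the instrument hold no expression values (unit other); they served to find the fluidics run (read from the gap between hybridisation times), the scan order and the group named for each array, per the file headers.

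Samples were grouped by their titles. The 64 control probe sets were set aside, which left 45037. Gene names came from the platform annotation: 34945 probe sets had 1 gene, 932 several and 9160 were not listed, and genes were named from the first kind only (18193 genes). Of those probe sets 34754 had an identifier in the RefSeq table of assembly GRCm38.p6, and 0 symbols changed through it. Genome coordinates were not used.

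Values were taken to log2(value + 16); a log2 fold change on this scale understates the change of dim probe sets. Probe sets with a mean above the median of all probe sets (a signal of about 22.6) were tested, 22518 in all. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a variance trend, Benjamini-Hochberg adjustment, threshold 0.05). A second count took unadjusted p under 0.01 with at least 1.5-fold. For gene lists each gene was represented by its probe set with the highest mean, which left 10757 genes above the filter, and 32 lists (25 of cell processes, 7 of markers of other cell types) were tested with limma's camera at a preset correlation of 0.01, with an estimated correlation and with fry. Members were also adjusted over each list alone. The values of 1 of the 32 lists are not reported here. Single values were compared with exact two-sided permutation tests, whose smallest p is 0.1 for 3 against 3 arrays. The design, the lists, the alternatives other than that of the first fluidics run alone, and the rule for named genes were fixed before the data were examined.

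The genes named are Itga7; the 15 highest and, of the genes that fell, all 14 past the adjusted threshold with groups that did not overlap; for each list, members past the test over the list alone, the 2 with the largest change and the 2 with the highest signal, from which examples are given; and Itgb1, Lama2, Dmd, Utrn, Dag1, Myod1, Myog, Myf5, Ccnd1, Bcl2, Bcl2l1, Akt1 and Ilk. A gene with a probe set past the threshold is given with that probe set unless another is stated.

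The steps were tested on simulated data. With 200 of 22518 probe sets changed in the comparison of induced and noninduced arrays (20 simulations), 8.98% of 1.25-fold, 39.0% of 1.5-fold and 73.0% of 2-fold changes were recovered, and 5.34% of the calls were false; with no change at most 1 probe set was called. A shift of the ATF4 list by 0.15 among 10757 genes passed in 100% of 50 simulations, with 0.04 other lists passing per simulation. The simulated variances followed a smooth trend with signal, as the fit assumes, so these rates do not test that assumption. The simulated noise was drawn separately for each gene, so the rates do not cover genes that vary together. The correlation estimated within the ATF4 list was 0.038, and other splits of the real arrays gave up to 4 lists.

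Alternatives were quantile normalization, median centring, no filter or a filter at the 75th percentile, pseudocounts of 1 and 64, no variance trend, robust moderation, array weights, the replicate number or the fluidics run as a block, leaving out each array, a threshold of 0.10, counting genes, an unmoderated test, the mean of a gene's probe sets, and, added after the data were seen, the 4 arrays of the first fluidics run alone.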

Results

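Gene expression was measured in C2C12 cells, a mouse line of skeletal muscle precursors (myoblasts), that carried a tetracycline-inducible integrin alpha7 construct. Integrin alpha7 is a laminin receptor subunit of skeletal muscle. Cells were kept undifferentiated for 36 h in medium with 20% serum, either without tetracycline (3 arrays) or with 1 µg/ml tetracycline (3 arrays), and the question was how raising integrin alpha7 affects transcription in myoblasts. The series describes the 3 samples of each condition as separate biological samples, so p-values for single probe sets measure the spread between such samples. Those of camera at the preset correlation set a list's genes against all other genes, and do not measure that spread. Each array gave a scaled, linear signal for 45101 probe sets, and the number of arrays limits the precision. The median signal was 24.99, 27.7 and 25.9 on noninduced arrays 1, 2 and 3 and 24.9, 22.9 and 22.9 on induced arrays 1, 2 and 3. Noninduced replicates 1 to 3 and induced replicate 1 were hybridised in one fluidics run and induced replicates 2 and 3 in a second one, and every noninduced array was scanned before every induced array, so scan order and group cannot be told apart.

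Itga7 transcript, the target of the construct, was not higher on the arrays labelled induced. Its probe set, 1418393_a_at, the single one for this gene on the array, gave 792 ± 17.2 (SD, n = 3) on the noninduced arrays and 693 ± 29.9 (SD, n = 3) on those labelled induced. All 3 arrays labelled induced lay below all 3 noninduced arrays, and the fitted level was 12.3% lower. The log2 fold change was -0.19 (SE 0.058, 95% interval -0.32 to -0.06), with an adjusted p of 0.178 in limma and p = 0.1 in an exact two-sided permutation test, the smallest p that 3 against 3 arrays allow. It was -0.23 for induced replicate 1 alone against the noninduced arrays of its fluidics run, and -0.10 after each array was centred on its median. The labels do not state the species of the construct or the part of the transcript it carries, and the probe sequences were not used here, so this probe set may check nothing. The treated group is therefore called the arrays labelled induced throughout, and every direction below rests on those labels.

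Among the genes past the adjusted threshold, Trib3, which encodes a pseudokinase induced by cell stress, showed the highest rise. Its signal went from 129.5 ± 7.06 (SD, n = 3) to 288 ± 34.6 (SD, n = 3), 2.08-fold (log2 1.06, SE 0.101, limma adjusted p = 0.0052). Cth, an enzyme of cysteine synthesis, rose by 0.70 on the log2 scale, and Chac1, which degrades glutathione, by 0.62. Stbd1, a glycogen-binding protein, also rose by 0.62. Snai2, a transcription factor of mesenchymal cells, rose by 0.59 and Ddit3, the stress factor CHOP, by 0.57. Rises of 0.40 to 0.53 were measured for Ndrg1, a hypoxia-responsive gene, Pck2, mitochondrial phosphoenolpyruvate carboxykinase, Ero1a, an oxidase of the endoplasmic reticulum, Nupr1, a stress-induced chromatin protein, and Xpot, the tRNA exporter.

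Some rises, that of Xpot among them, rested on 1 of several probe sets. Xpot rose by 0.40 with 1 probe set, and its other probe sets gave 0.19 and 0.12, neither past the test. Psip1, a chromatin-binding protein, rose by 0.54 with 1 probe set, and its other probe sets gave 0.17 and 0.15, neither past the test. Aebp1 rose by 0.64 with 1 probe set against 0.14 with the other. Tbc1d15 rose by 0.48 with 1 probe set, while the rest gave 0.07 and 0.03. The probe sets of Uba6, a ubiquitin-activating enzyme, ranged from 0.44, which passed, to -0.10, which did not.

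Kctd7, a potassium channel tetramerisation domain protein, fell most among the named genes. Its signal went from 309 ± 25.3 (SD, n = 3) to 159 ± 28.7 (SD, n = 3), a log2 fold change of -0.90 (SE 0.115, limma adjusted p = 0.0145). The other probe set of Kctd7 gave -0.52 and did not pass. Angptl4, a secreted inhibitor of lipoprotein lipase, fell by 0.69 and Tfrc, the transferrin receptor, by 0.47. The transcription factors Twist2, Klf10 and Jun fell by 0.44, 0.41 and 0.41, although the brighter Jun probe set gave -0.11 and did not pass. Fen1, a nuclease of DNA replication, fell by 0.40, Dynap by 0.37 and Tnfrsf12a, the TWEAK receptor, by 0.35. Hmgcs1 and Sqle, both enzymes of cholesterol synthesis, each fell by 0.34. Msl1, Arf2 and Etf1 fell by 0.55, 0.50 and 0.40 with 1 probe set each, and in all 3 genes another probe set had the opposite sign without passing.

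**Figure D1:**
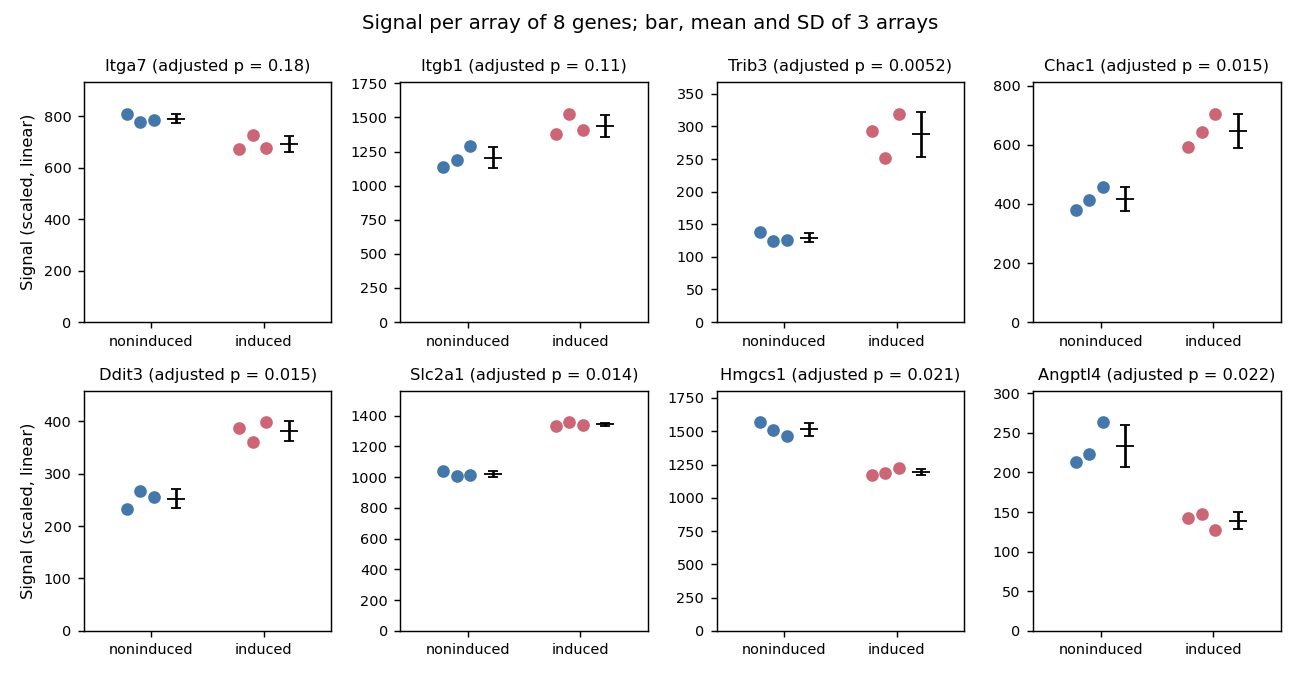
Scaled linear signal (y axis, from 0) of 8 genes on each of the 3 noninduced and 3 arrays labelled induced; each point is 1 array, and the bar beside the points gives the mean and SD. Itga7 lies lower on the arrays labelled induced (792 against 693), Trib3 higher (129.5 against 288), and the groups do not overlap in any of the 8 panels.

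In total 45 of the 22518 probe sets tested passed an adjusted p of 0.05 in limma, 27 higher and 18 lower on the arrays labelled induced. They stood for 24 genes that rose and 14 that fell, and 5 of the probe sets had several genes or none listed. The groups did not overlap in 20.3% of all tested probe sets, against 10% by chance. The changes were small: the median was 1.35-fold, 9 probe sets reached 1.5-fold and 2 reached 2-fold, and 98.9% of all tested probe sets lay within 1.5-fold. At an unadjusted p under 0.01 with a change of at least 1.5-fold there were 125 probe sets, 42 higher and 83 lower. These splits depended on the scaling: quantile normalization gave 28 and 21 adjusted calls and 62 and 50 unadjusted ones, and centring each array on its median gave 294 and 12 and 122 and 40, with the median log2 fold change of all tested probe sets at 0.08 in place of -0.01. The 45 calls became 0 in limma without a variance trend (2818 probe sets at an unadjusted p under 0.05, against 3305 in the fit reported here). They also became 0 with the fluidics run as a block (1918) and within the first run alone (1978), but the second run holds no noninduced array. Both of these fits, and every value below for the first run, therefore rest on induced replicate 1 as the single treated array. Leaving out 1 array gave 1 call without noninduced replicate 2, 2 without induced replicate 1, 9 without noninduced replicate 3 and 11 without induced replicate 2.

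Some quality measures of the arrays also differed between the groups. Gapdh, a housekeeping enzyme, had a 3′ to 5′ probe set ratio of 0.793 ± 0.0077 on noninduced arrays and 0.773 ± 0.011 on those labelled induced. Actb, cytoplasmic actin, had ratios of 1.103 ± 0.0045 and 1.13 ± 0.0146 (SD, n = 3 each). Neither pair of groups overlapped (exact permutation p = 0.1 for each), but the 2 ratios differed in opposite directions, and the cause was not tested. Of the bacterial and phage transcripts spiked into every sample, bioB was 0.38 higher and cre 0.21 higher on the log2 scale on the arrays labelled induced. These differences accompany every gene group below. Noninduced replicate 2 lay farthest out on the first principal component, which carried 29.7% of the variance.

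Genes of the ATF4 response, the transcriptional programme of amino acid and mitochondrial stress, were shifted upwards as a list. Of 21 list members tested, 4 rose past the test over all genes (Chac1, Ddit3, Pck2 and Nupr1), 17 did not pass and none fell; 15 rose when adjusted over the list alone. The latter also held Trib3 (0.70 with its brighter probe set), the folate enzyme Mthfd2 (0.34), the amino acid transporter subunit Slc3a2 (0.29), the cystine transporter Slc7a11 (0.55) and asparagine synthetase, Asns (0.14). Atf4 itself was at 0.09, the serine synthesis enzyme Phgdh at 0.08 and Psat1 at -0.05 (0.04 after median centring), none of them past either adjustment. The list median was 0.18, positive in 19 of 21 members, and camera with a preset correlation of 0.01 gave an adjusted p of 1.9e-14. The adjusted p was 0.0824 with an estimated correlation. The median was 0.28 after median centring and 0.20 for the single treated array of the first fluidics run.

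Genes of hypoxia and glycolysis were also shifted upwards. Of 18 tested, Slc2a1, the glucose transporter GLUT1, and Ndrg1 rose, 16 did not pass and none fell; 6 rose when adjusted over the list alone. The additional 4 were Vegfa (0.38), an angiogenic growth factor, Pdk1 (0.38), a kinase that inhibits pyruvate dehydrogenase, Hk2 (0.36), a hexokinase, and Bnip3 (0.31), a mitophagy receptor. Slc2a1 went from 1021 ± 18.4 to 1343 ± 11.7 (SD, n = 3 each), and its 3 probe sets were all positive. The brightest members, the glycolytic enzymes Pgk1 (0.00) and Ldha (-0.02, and 0.07 after median centring), did not pass. The list median was 0.12, with an adjusted p of 9.4e-06 in camera. The correlation estimated within this list was 0.19, far above the preset 0.01. With it camera gave an unadjusted p of 0.062 and an adjusted p of 0.395. The median was 0.11 within the first fluidics run, 0.22 after median centring and 0.08 without noninduced replicate 3.

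Genes of cholesterol synthesis were lower. All 17 members tested had a negative log2 fold change, with a median of -0.21. Hmgcs1, the synthase before the committed step, and Sqle, squalene epoxidase, fell past the test over all genes, 15 did not pass and none rose; 7 fell when adjusted over the list alone. Among the additional 5 were Sc5d (-0.40), Idi1 (-0.31) and Cyp51 (-0.27), and the bright farnesyl diphosphate synthase gene Fdps was at -0.15 and did not pass. Hmgcs1 went from 1515 ± 50.02 to 1194 ± 24.9 (SD, n = 3 each), and all 4 of its probe sets were negative. Camera gave the list an adjusted p of 2.7e-09. The adjusted p was 0.0826 with an estimated correlation. The median was -0.26 within the first fluidics run and -0.12 after median centring.

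Chaperones of the endoplasmic reticulum and genes of the fibrillar matrix were slightly lower as lists, and no member of either passed over all genes. Of 18 chaperone genes, 13 were negative (median -0.12); Calr (-0.19), Pdia3 (-0.16) and the transcription factor Xbp1 (-0.16) fell and Canx (0.19) rose when adjusted over the list alone, and the abundant Hspa5 (BiP) was at -0.12. Of 22 matrix genes, 17 were negative (median -0.11); Thbs1, thrombospondin, was the single member past the test over the list alone (-0.40), while Col1a2 was at -0.15, Col5a2 at -0.11 and Bgn at 0.30. Camera gave both lists an adjusted p of 0.0296. Both had an adjusted p of 0.30 with an estimated correlation. After median centring the medians were -0.03 and -0.01, with adjusted p of 0.289 and 0.210. Without noninduced replicate 2 the adjusted p was 0.0620 for the chaperones and 0.0830 for the matrix. For the chaperones it was 0.103 without noninduced replicate 1 and 0.0804 without induced replicate 1, and the matrix median was -0.06 for the single treated array of the first fluidics run.

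**Figure D2:**
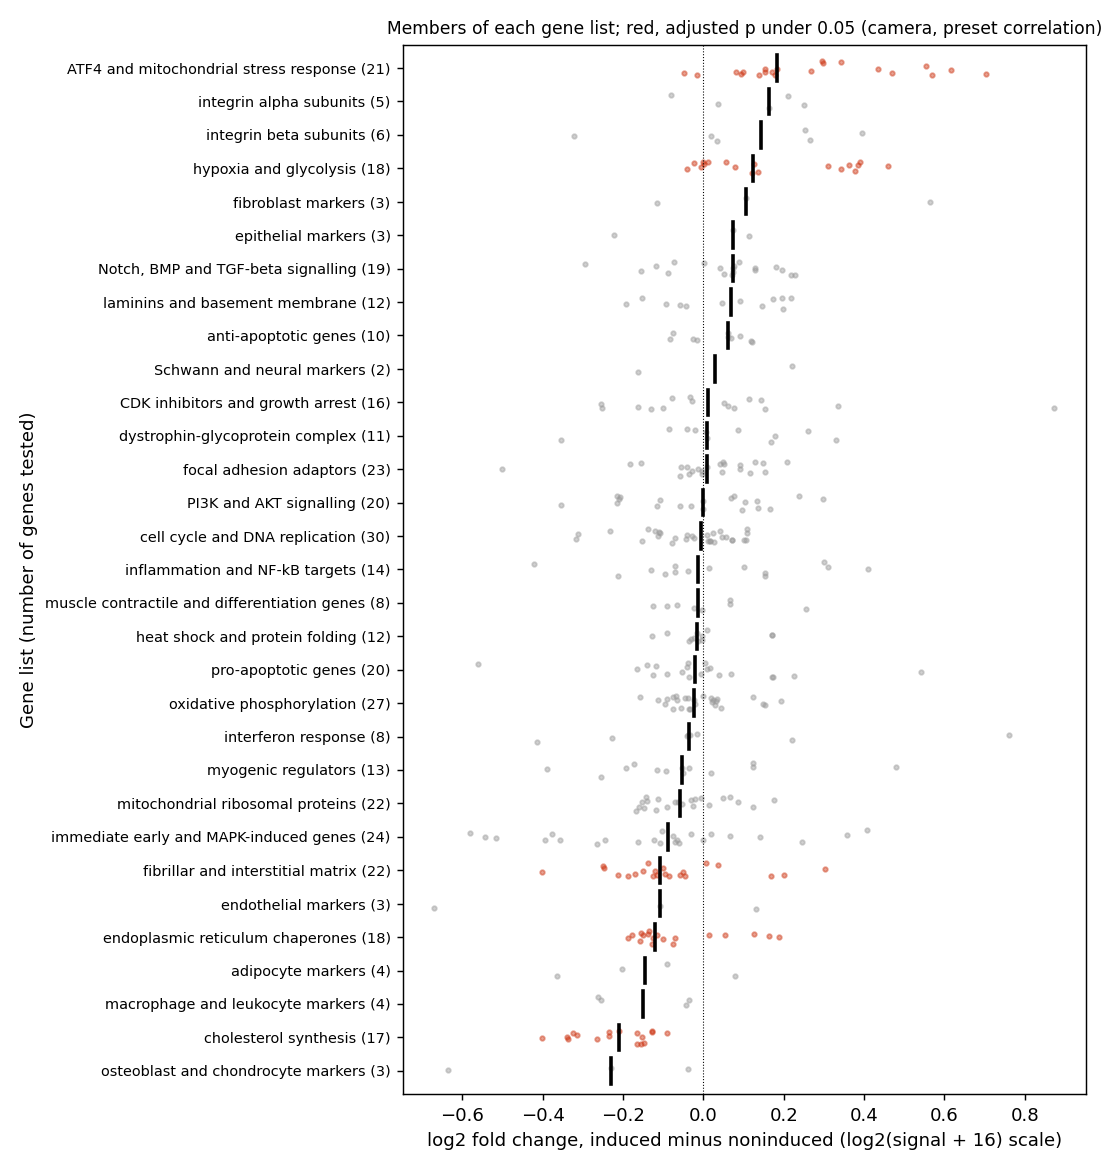
Log2 fold change of each tested member (points) of 31 gene lists, arrays labelled induced minus noninduced, with the list median as a black bar; lists in red passed an adjusted p of 0.05 in camera with a preset correlation. The ATF4 list has its median at 0.18, hypoxia and glycolysis at 0.12 and cholesterol synthesis at -0.21, and no list passed with an estimated correlation.

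Integrins and their partners did not pass the test over all genes. Itgb1, the beta1 subunit that pairs with integrin alpha7, gave 1205 ± 76.5 on the noninduced arrays and 1438 ± 79.9 on those labelled induced (SD, n = 3 each; log2 0.25, limma adjusted p = 0.110), and it was the single one of 6 beta subunits to pass over the list alone. Itga6 (0.25), another laminin receptor subunit, was the single one of 5 other alpha subunits to do so, while Itgav was at 0.04, Itga2b at 0.21, Itgb3 at 0.39, Itgb5 at 0.03 and Itgb6 at -0.32. The medians were 0.16 for the alpha and 0.14 for the beta list (camera adjusted p 0.321 and 0.197), and neither was stable. The alpha median was 0.05 without noninduced replicate 3, 0.27 without noninduced replicate 1 and -0.03 with no filter on dim probe sets, and the beta median was 0.01 within the first fluidics run. In the laminin and basement membrane list (12 tested, median 0.07), Nid1 (0.22) and Col4a1 (0.20) passed over the list alone; the median was 0.03 without induced replicate 1, 0.04 without noninduced replicate 1 and -0.05 with no filter. Utrn, the dystrophin homologue utrophin, passed over the list alone in the dystrophin-glycoprotein list (0.26). That list had 11 tested members and a median of 0.01, which was 0.10 after median centring. Its member Dag1, dystroglycan, was at 0.01 (-0.01 after quantile normalization). Lama2 and Dmd lay below the signal filter, at 19.9 and 10.8 on the noninduced arrays. Among 23 focal adhesion adaptors (median 0.01), the integrin-linked kinase gene Ilk (-0.18) and Bcar1 (-0.50) were lower and Lims1 (0.21) and filamin, Flna (0.15), higher past the test over the list alone.

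Myogenic genes and the genes of proliferation and survival gave no list past the test. Myod1, a master regulator of myogenesis, was at -0.17 (limma adjusted p = 0.258), Myf5 at 0.12 and Myog, which marks differentiation, at -0.25 with signals of only 42.8 and 32.9. Of 13 myogenic regulators (median -0.05, and 0.04 after median centring), Hes1, a Notch target, passed over the list alone (-0.39). None of 8 contractile and differentiation genes did (median -0.01). Of 30 cell cycle genes 15 were positive and 15 negative (median -0.01): Aurka (-0.23) and Ccne1 (-0.31) passed over the list alone, and Ccnd1, cyclin D1, was at 0.06, Pcna at -0.12 and Rrm2 at 0.01. Among 16 genes of growth arrest (median 0.01), Gadd45a was at 0.87 (limma adjusted p = 0.0537) and Gadd45g at -0.26, both past the test over the list alone. No pro-apoptotic (20 tested, median -0.02), anti-apoptotic (10 tested, median 0.06, and -0.01 without induced replicate 3) or PI3K and AKT gene (20 tested, median 0.00) passed either adjustment; Bcl2 was at 0.06, Bcl2l1 at 0.12 and Akt1 at -0.06 (0.03 after median centring).

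Immediate early genes lay on both sides of 0. Of 24 members, 17 were negative (median -0.09, and 0.00 after median centring; camera adjusted p = 0.184). Without induced replicate 2 the list was past the threshold in camera with a preset correlation (median -0.15, adjusted p = 0.0160). With an estimated correlation on all arrays the adjusted p was 0.642. The median was -0.15 without noninduced replicate 2, which did not pass. The single treated array of the first fluidics run gave -0.14, and the fits that rest on it passed too (adjusted p = 0.0132 with the run as a block, 0.0041 within the first run). Egr1 was at -0.54 (limma adjusted p = 0.0515) and Fos at -0.58, and both were lower past the test over the list alone, as were Junb (-0.27) and Egr3 (-0.36), while Klf4 (0.41) and Dusp4 (0.36) were higher. In the remaining lists of cell processes no list passed: the medians were -0.02 for oxidative phosphorylation, -0.06 for mitochondrial ribosomal proteins, -0.03 for the interferon response, -0.01 for inflammation and NF-kB targets, 0.07 for Notch, BMP and TGF-beta signalling and -0.01 for heat shock proteins. Without induced replicate 3 the mitochondrial ribosomal proteins were past the threshold in camera with a preset correlation (median -0.10, adjusted p = 0.0117). With an estimated correlation on all arrays the adjusted p was 0.769. Their median was -0.02 without induced replicate 2 (adjusted p = 0.441) and 0.03 after median centring. The single treated array of the first run gave -0.09, and here too the fits that rest on it passed (adjusted p = 0.0335 with the run as a block, 0.0329 within the first run). Leaving out 1 array moved other medians as well: the interferon median was 0.00 without induced replicate 2 and -0.10 without induced replicate 3, and the Notch, BMP and TGF-beta median was 0.03 without noninduced replicate 3. After median centring the oxidative phosphorylation median was 0.07. Over the lists alone, Atp5o (0.19), Bst2 (0.76), Ptgs2 (0.31) and Nfkbia (-0.21) passed, Bst2 with signals of only 19.0 and 42.1.

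Markers of other cell types showed no shift past the test. The medians were 0.11 for fibroblasts, -0.15 for adipocytes, -0.23 for osteoblasts and chondrocytes, -0.15 for macrophages and leukocytes, -0.11 for endothelium, 0.03 for Schwann and neural cells and 0.07 for epithelium, each from 2 to 4 genes above the filter. Single arrays moved them: the osteoblast and chondrocyte median was -0.06 without induced replicate 1 and -0.37 without induced replicate 2. Without noninduced replicate 2 the endothelial median was 0.07 and the epithelial one -0.02. Pdgfra, a fibroblast receptor, was at 0.56, Sp7, an osteoblast factor, at -0.64 and Ncam1, which myoblasts also express, at 0.22, and these 3 passed over their lists alone. Sp7 was dim, with mean signals of 62.8 and 34.1, and its groups overlapped. Over the 27 lists that did not pass, the camera adjusted p lay between 0.184 and 0.985.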

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

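The comparison of spiked controls, the tests on Itga7, and the counts of splits of the arrays other than that of gene lists were chosen only after the results were seen.

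Bacterial and phage transcripts added to every sample, which belong to no comparison of mouse genes, gave a higher signal on the arrays labelled induced. Of the hybridisation controls, bioB was higher by 0.38, bioC by 0.25, bioD by 0.28 and cre by 0.21 on the log2 scale. Of the labelling controls, dap was higher by 0.36, phe by 0.32, thr by 0.19 and lys by 0.15. The remaining labelling control, trp, was dim (signals of 2.59 and 4.38), and its difference of 0.13 did not separate the groups (exact permutation p = 0.3). In 7 of these 9 every array labelled induced lay above every noninduced array (exact permutation p = 0.1, the smallest possible), the exceptions being lys (exact p = 0.2) and trp.

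The Itga7 probe set was lower on the arrays labelled induced, opposite to the direction that induction of its transcript would give. An exchange of group names after scanning is argued against by the instrument's own record, which names the labelled group for 6 of 6 arrays; an exchange of cultures before that is not covered. Scaling as the whole cause is argued against too: after quantile normalization, Itga7 lay at -0.20 relative to the median of all tested probe sets (SE 0.057). A part in the size of the fall itself stays open, since centring each array on its median brought it to -0.10 (limma adjusted p = 0.550). That centring also moved the median of all tested probe sets from -0.01 to 0.08. It thus does not bear on the change relative to that median. It stays open whether the 1 probe set of Itga7 on the array detects the transcript of the construct, since neither is described. Induction may thus be invisible to this probe set, and the tables hold no other measure of it.

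The ATF4 list was higher on the arrays labelled induced. After quantile normalization its median lay 0.17 above that of all tested genes. That is outside the range of 95% of 10000 lists matched on signal (-0.07 to 0.06). It argues against array scaling as the source of a rise relative to other mouse genes. A difference common to the whole array is not covered. The spiked controls were higher on average on the arrays labelled induced, by 0.13 for trp to 0.38 for bioB, and the groups overlapped for lys and trp. The list was not compared with these controls. A stress of the endoplasmic reticulum that raises its chaperones is argued against by their median of -0.12, which lay below a level of 0.09. That level follows from the ATF4 median of these same data, by a rule set beforehand. The 95% bootstrap range of the chaperone median was -0.14 to -0.03. It resamples genes, which are not independent replicates, and holds no spread between arrays. A stress of this compartment without a rise of its chaperones is not covered. Ero1a, an oxidase of the endoplasmic reticulum, rose by 0.44 and Ddit3 by 0.57. A difference of the second fluidics run stays open: induced replicate 1, hybridised with the noninduced arrays, had a list median of 0.20 against them, where these differed from each other by -0.01 to 0.02, but it is a single array. An effect of tetracycline itself, which can inhibit mitochondrial translation, also stays open as a hypothesis, and cannot be told apart from an effect of the integrin, because 0 arrays were of cells given tetracycline without the construct.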

How the results depend on the processing

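The alternative restricted to the first fluidics run was added only after the data were seen, and the ATF4 list was made a result of its own only then, under alternatives fixed before. A looser threshold admits more calls by construction, and elsewhere the cause was not tested. The run as a block and the first run alone both rest on induced replicate 1 as the only treated array, so they count as 1 weak test. The Itga7 log2 fold change stayed negative and not past the threshold in all 20 settings (-0.10 to -0.23). The 45 adjusted calls became 306 with median centring, 1 with no filter, 103 above the 75th percentile, 0 without a trend, 76 with robust moderation, 88 with array weights, 0 with the run as a block, 239 at a threshold of 0.10, 80 when genes were counted, 2 in the unmoderated test and 0 in the first run alone; leaving out 1 array gave 58 without noninduced replicate 1, 50 without induced replicate 3 and 1 to 11 otherwise. Quantile normalization (49) and pseudocounts of 1 (43) and 64 (49) moved them little. The 125 unadjusted calls became 351 with no filter, 14 above the 75th percentile and 8 with a pseudocount of 64. The 5 lists became 3 with median centring, without a trend and with the mean of a gene's probe sets, and 0 with an estimated correlation (4 at an unadjusted p under 0.05; fry gave 4); leaving out 1 array gave 3 to 6. The ATF4, hypoxia and cholesterol lists passed in all 18 settings with a preset correlation. The ATF4 median of 0.18 ranged from 0.17 to 0.28, and lost its call with an estimated correlation (0.18, adjusted p = 0.0824). Its 15 members past the test over the list alone became 5 with the run as a block and 8 in the first run. With the replicate block 7 probe sets were called; arrays of the same number deviated together with correlations of 0.01, -0.06 and -0.01, and 1 of 6 arrays correlated best with its own number, so the arrays were not taken as paired. Of 527 alternative values of the 31 named genes past the threshold, 252 kept their sign but were no longer past it, and 0 reversed. Among the 186 of these values with 1 array left out, 126 were no longer past it. Camera has no robust option and was not run with it. Dim signals limit Myog, other dim named genes and the probe sets below the filter. Mean signals on noninduced arrays and those labelled induced were 19.0 and 42.1 for Bst2 and 25.8 and 45.6 for Slc7a11. They were 35.9 and 25.2 for Itgb6, 49.3 and 80.6 for Pdgfra, and 61.0 and 35.8 for Fos.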

Other observations

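The lists in the next paragraphs and the counts of splits, apart from that of gene lists, were chosen only after the calls were seen, and 1 member, Hspa9, was itself among the calls.

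Aminoacyl-tRNA synthetase genes, which charge tRNAs with amino acids, divided by whether they are known ATF4 targets. All 12 known targets tested were positive, with a median of 0.15: Iars was at 0.33, Eprs at 0.21, Sars at 0.19 and Gars at 0.16. Of 7 other synthetases 3 were positive and the median was -0.07, with Kars at -0.08 and Rars at 0.07. The difference of the medians was 0.22 (p = 0.00089, permutation of genes, which are not independent replicates). No single synthetase passed over all genes, and the values are consistent with the hypothesis that ATF4 target genes outside the first list were higher too.

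Mitochondrial chaperones and proteases were weighed as a sign of mitochondrial protein stress, which may accompany inhibited mitochondrial translation. Their median was 0.0925, at percentile 98.4 of 10000 lists matched on signal. The 95% bootstrap range over the 12 members was -0.01 to 0.14, and limma's camera gave an unadjusted p of 0.050. Hspa9, the mitochondrial Hsp70, rose (0.33, limma adjusted p = 0.0145). The mitochondrial chaperones Hspd1 and Hspe1 were at -0.02 and 0.00, and Clpp, a protease of the same response, was at -0.24 without passing. The list thus stands only just above matched lists.

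The 10 splits of the 6 arrays into 3 and 3 are too few for a share under 0.05. In each of the 6 results, 1 split, the real one, gave a value as large. The real split gave 45 adjusted calls against at most 1 in any other split, 125 unadjusted calls against 62, and 5 lists against 4. The absolute list medians were 0.18 against 0.11 for ATF4, 0.12 against 0.07 for hypoxia and 0.21 against 0.14 for cholesterol synthesis.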
